A study of Mus musculus with 6 samples.

How the data were processed

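Total RNA of 1 snap-frozen colorectal adenoma per mouse was hybridised to Affymetrix Gene 2.0 ST arrays, per the labels. The deposited values are log2 signals, 1 per transcript cluster and array. They came from Affymetrix Expression Console 1.4, per the submitters' processing notes. The background correction, summarisation and annotation version are not given in the sources used here. The values of the 6 arrays had nearly the same distribution, and their base was taken as 2 because the deposited fold equals 2 to the power of the difference of group means, to within 0.005.

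The authors also deposited a workbook with the log2 signals, group means, a signed fold score and an unadjusted p-value per cluster, per the file headers. Its log2 signals were identical to those of the series table (largest difference 0) for 33648 clusters, and 1 row was empty. The column headed as the control mean held the FoxO1ADA mean and the one headed as the sample mean held the wildtype mean (largest difference 0.005 from the means computed here), so a positive fold score in the deposited workbook means higher in FoxO1ADA. The signal columns of the FoxO1ADA samples were headed KO, although the labels name FoxO1ADA, and were matched through the sample descriptions. The deposited p-value differed by more than 1% from an unequal-variance test of the same signals in 2 rows. The deposited fold and p-value were used only for the counts credited to the authors' deposited table.

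Gene symbols were taken from the workbook and updated through a GRCm38.p6 RefSeq gene table. Of 33649 clusters, 27739 had a gene name: 23166 carried a current symbol, 2545 were updated through 1 older symbol and 2028 kept the file's symbol. The other 5910 clusters had no gene symbol. The 27739 named clusters gave 25240 genes, of which 1717 had more than 1 cluster. The build of the coordinates is not stated. Of 25649 clusters with a unique gene in the GRCm38.p6 table, 95.7% overlapped it, so coordinates are given as GRCm38, which is an inference. Of 695 tested list members, 7 were represented by a cluster outside the gene of that name (Top2a, Loxl2, Gapdh, Pgam1, Cycs, Cox6c and Cd209a). The bounds of the 3 immunoglobulin loci came from the same table.

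Tested genes were clusters with exactly 1 symbol, 1 per gene (the one with the highest mean over the 6 arrays), with a mean at or above the median of all cluster means, 4.693, which left 14529 genes. FoxO1ADA and wildtype tumours were compared with limma 3.58.1 in R (lmFit and eBayes, no block, two-sided, prior degrees of freedom 2.84) with Benjamini-Hochberg adjustment and a threshold of 0.05. The median log2 difference over all tested genes was 9e-04. No background level was available for the arrays, so folds against a group mean below the filter are lower bounds, with that group's arrays below the filter set to it. Single values also had exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3. A total of 38 gene lists was fixed before the data were examined. Lists with at least 5 tested members (37) were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Immunoglobulin clusters were summarised from a fit of all clusters, with or without a gene symbol.

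Genes were named by a rule fixed before the data were examined. It took Foxo1, then per direction 15 genes with the widest log2 difference among genes past the adjusted threshold whose groups did not overlap, filled up from genes at an unadjusted p under 0.01 without overlap, and in each list up to 4 members with the smallest p and any member past the threshold adjusted over the list alone. Predicted loci, noncoding small RNAs, receptor families and immunoglobulin segments were passed over for the first part. Some genes that the rule selects are not reported here. Muc2, Irs2 and the Snrpn cluster on chromosome 7 were named in addition, after their values were seen. So were the immunoglobulin segments past the threshold, which the files name only by database identifiers and which are therefore given by position.

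The gene test was checked on simulated data with the means of the 14529 genes, 3 against 3 arrays and 200 changed genes in each of 20 data sets. The simulated spread was limma's moderated one, normal and equal in both genotypes. The gene test found 21.0% of genes changed 1.5-fold, 80.4% of those changed 2-fold and 97.9% of those changed 4-fold, and 5.59% of its calls were false. The tumours had unequal spread, for Jchain an SD of 0.44 in FoxO1ADA and 2.30 in wildtype. These shares are therefore not detection rates for the tumours: Jchain, 12.8-fold higher, did not pass. In the same simulation, in which genes varied independently, camera made 4 calls in 740 list tests with no list changed, and it called a goblet list raised by 0.5 in all 20 data sets. These counts do not check the preset correlation for lists whose genes vary together, such as the goblet list (estimated correlation 0.385).

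The alternatives were no filter, a filter at the 75th percentile, all transcript clusters, a further quantile normalization, centring on array medians, the workbook's signals, an intensity trend with a robust prior, array weights, the mouse number as a block, leaving out each tumour, a plain equal-variance test, and the other list tests. A run without the immunoglobulin loci was added after seeing the data. Scanner files were not analysed here.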

Results

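Gene expression was measured on Affymetrix Gene 2.0 ST arrays in 6 colorectal adenomas of female C57BL/6N mice, 1 tumour per mouse. All mice had received the carcinogen AOM (10 mg/kg on day 1) and the colitis-inducing agent DSS (1.5% in the drinking water on days 5 to 11), and tumours were taken 62 days after AOM. 3 tumours came from mice with FoxO1ADA, a constitutively active form of the transcription factor FoxO1, and 3 from wildtype mice. The labels used here do not state which cells carried the variant. Log2 signals of 33649 transcript clusters were deposited, with array medians from 4.66 to 4.73, and 14529 genes were tested. The number of arrays, 3 per genotype, limits the precision of every value. The comparison asks how FoxO1ADA changes the gene expression of tumours that arise on colitis.

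The 3 FoxO1ADA tumours resembled each other more closely than the wildtype tumours did. Over the tested genes, Pearson's r across genes was 0.981 to 0.983 among the FoxO1ADA tumours, 0.941 to 0.965 among the wildtype tumours and 0.944 to 0.963 between the genotypes. Genes are not independent replicates, so these values describe the arrays only. The first principal component held 37.6% of the variance and the second 29.2%. Wildtype replicates 1 and 3 scored 27.2 and 30.6 on the first component, while wildtype replicate 2 scored -10.3, next to the FoxO1ADA tumours (-24.3 to -10.6). Wildtype replicate 2 stood apart on the second component, at -37.7. It also had the highest squamous epithelium mean of the 6 tumours, 7.99 on the log2 scale against 5.67 to 6.61 in the others.

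Foxo1 itself had similar signals in both genotypes. Its cluster on the plus strand of chromosome 3 (52268337 to 52350109) read 7.12 ± 0.19 (SD, n = 3) in FoxO1ADA and 7.06 ± 0.06 (SD, n = 3) in wildtype tumours. The log2 difference was 0.06, with a 95% confidence interval from -0.23 to 0.35 (limma adjusted p = 0.941), and the exact two-sided permutation p was 0.7, where 3 against 3 cannot go below 0.1. A second cluster named Foxo1, on the opposite strand (52268435 to 52269435), read 5.31 ± 0.03 in FoxO1ADA and 5.48 ± 0.05 in wildtype (SD, n = 3, exact permutation p = 0.1). Whether the probes match the variant's transcript is not given in the sources used here, so the Foxo1 signal does not check the labels.

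**Figure D1:**
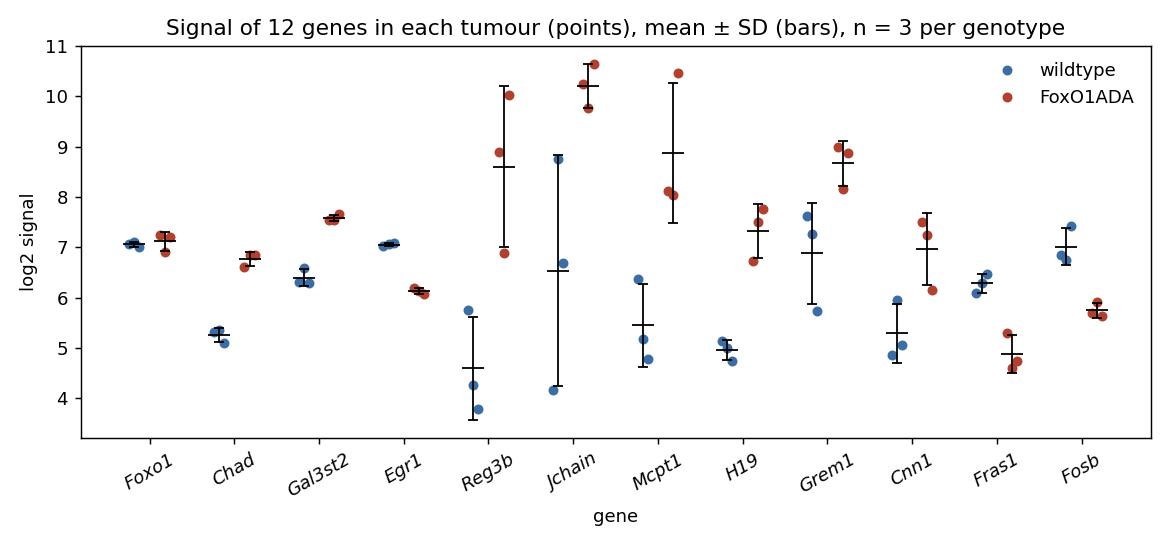
Log2 signal (vertical axis) of 12 genes in each of the 3 wildtype (blue) and 3 FoxO1ADA (red) tumours, with mean and SD as black bars. Foxo1 overlaps between the genotypes, Chad, Gal3st2 and Egr1 separate with a small spread, and the wildtype spread of Jchain is wide (SD 2.30).

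Chad, Gal3st2 and immunoglobulin gene segments rose in FoxO1ADA tumours and Egr1 fell. Chad encodes chondroadherin, a leucine-rich matrix protein, and read 6.76 ± 0.14 in FoxO1ADA and 5.26 ± 0.14 in wildtype tumours (SD, n = 3), a 2.83-fold difference (limma adjusted p = 0.0233). Gal3st2, a sulfotransferase that acts on galactose residues of glycans, was 2.28-fold higher (7.59 ± 0.06 against 6.40 ± 0.17, limma adjusted p = 0.0455). Egr1, an immediate early transcription factor, was 1.89-fold lower (6.13 ± 0.06 against 7.05 ± 0.03, limma adjusted p = 0.0455). The other 4 genes past the threshold lay inside immunoglobulin loci: a pair of heavy chain segments on chromosome 12, higher by at least 5.84-fold (start 113948282) and by 7.14-fold (start 113685482), and a pair of kappa segments on chromosome 6, higher by 7.39-fold (start 69184826) and by at least 4.91-fold (start 69016560). A fold is given as a lower bound where the lower group's mean was below the filter, with its arrays below the filter set to it. Chad lies on chromosome 11 (94565047 to 94569127), Gal3st2 on chromosome 1 (93861344 to 93876494) and Egr1 on chromosome 18 (34861207 to 34864984). Altogether 7 of 14529 genes passed an adjusted p of 0.05 in limma, 6 higher and 1 lower. With the deposited values quantile-normalized again, 8 passed (6 higher, 2 lower), with arrays centred on their medians 5 passed (5 higher, 0 lower), and with the clusters of the immunoglobulin loci left out, an alternative chosen after seeing the data, limma called 0 (1020 at an unadjusted p under 0.05). The count was 1 without FoxO1ADA replicate 1, 3 without FoxO1ADA replicate 3, 3 without wildtype replicate 1, 36 without wildtype replicate 2 and 2 without wildtype replicate 3, and Chad, Gal3st2 and Egr1 missed the threshold whenever a tumour other than wildtype replicate 2 was left out.

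Immunoglobulin genes had higher signals in FoxO1ADA tumours nearly throughout the 3 loci. Of 153 clusters inside the 3 loci with a signal at or above the filter, 149 were higher and 4 lower in FoxO1ADA tumours, and 132 of the higher ones reached an unadjusted p under 0.05. The median difference over these clusters was 7.58-fold, at 8.82-fold for the kappa locus (71 clusters), 7.05-fold for the heavy chain locus (78 clusters) and 6.27-fold for the lambda locus (4 clusters). The wildtype mean of 57 of the 153 clusters was below the filter, and the median of lower bounds over all 153 was 6.11-fold. The mean log2 signal of the 153 clusters was 8.15 ± 0.38 in FoxO1ADA and 5.39 ± 0.97 in wildtype tumours (SD, n = 3, exact permutation p = 0.1). Jchain, which joins polymeric IgA and IgM, was 12.8-fold higher (10.2 ± 0.44 against 6.54 ± 2.30, limma adjusted p = 0.562), a difference that did not pass the adjusted threshold.

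A wider group of genes had a difference of at least 1.5-fold at an unadjusted p under 0.05, which is not corrected for the number of genes: 308 genes, 224 higher and 84 lower. Of these, 45 lay inside immunoglobulin loci. At an unadjusted p under 0.05 alone there were 1059 genes, where chance gives 726 on average. The groups did not overlap for 1857 genes (12.8%, where chance gives 10% on average). Genes vary together, so chance counts can lie far from these averages, and neither comparison tests for an excess. Another split of the 6 tumours into 3 and 3 gave 293 genes at 1.5-fold, against 308 for the genotypes. The authors' deposited table held 261 clusters at its own p under 0.05 and at least 1.5-fold, 215 higher and 46 lower in FoxO1ADA, and 125 of the 308 genes also met both limits in the authors' deposited table. The count of 308 became 546 without wildtype replicate 1 and 628 without wildtype replicate 2.

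Among the genes named by size, those higher in FoxO1ADA tumours included antimicrobial, mast cell and smooth muscle genes, but none except Chad and Gal3st2 passed the adjusted threshold. Reg3b, an antimicrobial lectin, was at least 11.8-fold higher (8.61 ± 1.60 against 4.59 ± 1.03, SD, n = 3) and the mucosal mast cell chymase Mcpt1 was 10.8-fold higher (8.87 ± 1.39 against 5.45 ± 0.83). H19, an imprinted long noncoding RNA, was 5.15-fold higher (limma adjusted p = 0.0642). A cluster that the files name Snrpn was at least 2.74-fold higher (limma adjusted p = 0.0714), but it lies on chromosome 14 (62540339 to 62541586), outside the imprinted Snrpn gene on chromosome 7, whose own cluster (59982501 to 60140219) read 4.97 ± 0.25 in FoxO1ADA and 4.69 ± 0.47 in wildtype tumours (SD, n = 3). Secretory products in the group were Scgb2b7 (3.83-fold), Sval1 (3.68-fold), the trypsin inhibitor Spink1 (3.13-fold) and Lbp, the lipopolysaccharide-binding protein (3.03-fold). Capn6 was 3.77-fold higher, the BMP antagonist Grem1 3.46-fold, the smooth muscle gene Cnn1 3.17-fold and the glycosyltransferase gene B4galnt2 3.02-fold. Absence of overlap between the groups was a condition of the naming rule. For the 13 genes other than Chad and Gal3st2, limma adjusted p ran from 0.0642 for H19 to 0.562 for Jchain.

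The genes named by size on the lower side were smaller in fold. Fras1, a basement membrane protein, was 2.64-fold lower (4.88 ± 0.37 against 6.28 ± 0.19, SD, n = 3) and the AP-1 subunit gene Fosb 2.40-fold lower (5.75 ± 0.15 against 7.01 ± 0.37). The EGF receptor ligand Hbegf was 1.78-fold lower and the activin antagonist Fst 1.97-fold lower. Keratinization and epithelial genes were Krt36 (2.21-fold), the connexin gene Gjb5 (at least 1.53-fold) and the transglutaminase gene Tgm1 (1.86-fold). Further genes were Tppp (2.41-fold), Ccdc85b (1.96-fold), Moxd1 (1.94-fold), Isl1 (1.92-fold), Kcnb2 (1.87-fold) and Avil (1.86-fold). Apart from Egr1, limma adjusted p ran from 0.0642 for Moxd1 to 0.552 for Gjb5 and Avil, so these differences did not pass.

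Goblet cell and antimicrobial genes were shifted upward in FoxO1ADA tumours when gene lists fixed beforehand were compared with all other genes. All 23 tested members of the goblet and mucus list were higher, with a median log2 difference of 0.71 (camera adjusted p = 1.01e-07, adjusted p = 0.77 with an estimated correlation). Among them were Creb3l4 (1.06 on the log2 scale), Best2 (1.12), Reg4 (1.25) and Ccl6 (0.99), while the major mucin Muc2 read 12.8 ± 0.21 against 12.1 ± 0.61 (SD, n = 3). 8 members reached an unadjusted p under 0.05, 0 passed over all genes and 1, Creb3l4, passed when adjusted over the list alone (limma adjusted p = 0.0178). The per-tumour list mean was 8.74, 9.04 and 8.86 in FoxO1ADA and 7.70, 8.86 and 7.96 in wildtype replicates 1, 2 and 3 (exact permutation p = 0.2). Of 20 tested antimicrobial and Paneth genes, 17 were higher, with a median of 0.74 (camera adjusted p = 3.6e-06, adjusted p = 0.77 with an estimated correlation), and 1, Reg3b, passed when adjusted over the list alone (limma adjusted p = 0.0438), 0 over all genes. The list mean was 9.83, 9.64 and 9.49 in FoxO1ADA and 9.42, 8.64 and 7.90 in wildtype replicates 1, 2 and 3, and the difference of the means, 1.00, became 0.63 without wildtype replicate 3. Log2 differences were 1.12 for Ang4 and 1.88 and 1.66 for the defensins Defa17 and Defa24. Absorptive colonocyte genes were not called as a list: 11 of 33 were higher and 22 lower, with a median of -0.12 (camera adjusted p = 0.316). In this list 0 members passed over all genes or adjusted over the list alone. The direction hung on 1 tumour. The difference of the list means was -0.116 with all tumours, 0.115 without wildtype replicate 2 and -0.342 without wildtype replicate 1. The log2 differences of Car2, Sgk1, Hsd11b2 and Slc9a3 were -0.48, -0.64, 0.68 and -1.20.

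Genes of smooth muscle, of B and plasma cells and of mast cells were also higher as lists. In the smooth muscle list 14 of 18 tested members were higher (median 0.31, camera adjusted p = 6.81e-05, adjusted p = 0.77 with an estimated correlation), and 4 passed when adjusted over the list alone, 0 over all genes. These were the actin genes Actg2 (1.22 on the log2 scale) and Acta2 (0.88), the calponin gene Cnn1 (1.67) and Kcnmb1 (0.47). In the B and plasma cell list 5 of 6 tested members were higher (median 0.84, camera adjusted p = 0.000474, adjusted p = 0.77 with an estimated correlation), and Mzb1 (1.86-fold), Cd79a (at least 1.63-fold), Jchain (12.8-fold) and Pou2af1 (at least 1.38-fold) made 4 past the threshold adjusted over the list alone, 0 over all genes. In the mast cell list 5 of 6 were higher (median 1.22, camera adjusted p = 0.0121, adjusted p = 0.77 with an estimated correlation). Kit (0.93), Mcpt1 (3.43), Mcpt2 (2.64) and Hdc (-0.92), the histamine-forming decarboxylase, were the 4 past the threshold adjusted over the list alone, 0 over all genes. The mast cell list mean was 6.62, 6.40 and 8.26 in FoxO1ADA and 5.96, 5.21 and 6.07 in wildtype replicates 1, 2 and 3, so much of the shift came from FoxO1ADA replicate 3: the difference of the means was 1.35 with all tumours and 0.77 without it (camera adjusted p = 0.0158). Without wildtype replicate 2 the mast cell list lost its call (camera adjusted p = 0.134), as the smooth muscle list did under the stricter filter (0.116).

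Lists shifted downward held cell junction, squamous and neutrophil genes. In adherens junctions and desmosomes 18 of 20 members were lower, by a median of -0.16 (camera adjusted p = 0.000415, adjusted p = 0.77 with an estimated correlation). The plakophilin gene Pkp3 differed by -0.61, Jup by -0.26, Dsg2 by -0.30 and Ppl by -0.55, with 0 past the threshold over all genes or adjusted over the list alone. In squamous epithelium 8 of 10 were lower (median -0.85, camera adjusted p = 0.0154, adjusted p = 0.908 with an estimated correlation), among them the keratins Krt14 (2.66-fold lower), Krt6a (3.54-fold) and Krt4 (2.83-fold) and the desmoglein Dsg3 (2.10-fold), with 0 past either threshold, over all genes or adjusted over the list alone. In neutrophils 11 of 13 were lower (median -0.28, camera adjusted p = 0.0172, adjusted p = 0.908 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The log2 differences of Hdc, Asprv1, G0s2 and Il1r2 were -0.92, -0.93, -0.28 and -0.35. Wildtype replicate 2 carried most of the squamous difference: the difference of the list means was -0.81 with all tumours and -0.27 without it (camera adjusted p = 0.505), and camera adjusted p was 0.0657 without FoxO1ADA replicate 3. For junctions that difference was -0.19 and, without wildtype replicate 2, -0.11 (camera adjusted p = 0.134). For neutrophils it was -0.30 and, without FoxO1ADA replicate 3, -0.11 (camera adjusted p = 0.349), but -0.54 without wildtype replicate 2 (camera adjusted p = 0.000158), with camera adjusted p = 0.324 without wildtype replicate 1 and 0.0648 without wildtype replicate 3.

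**Figure D2:**
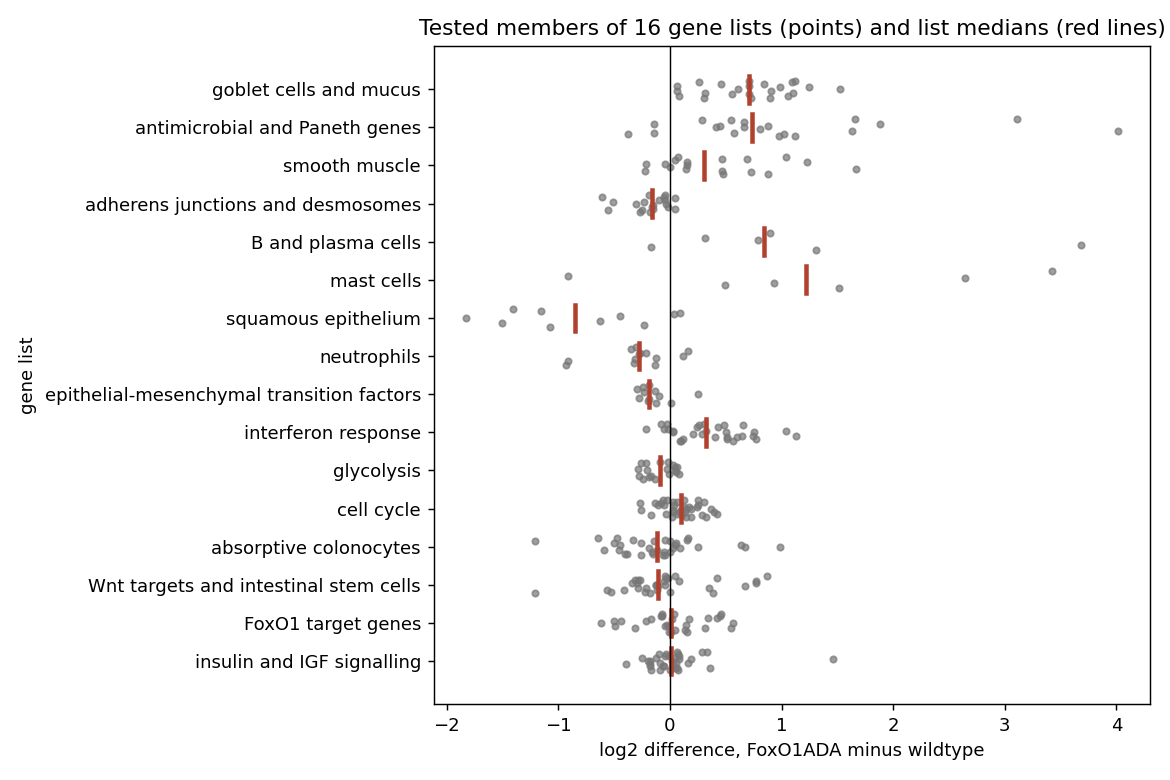
Log2 difference, FoxO1ADA minus wildtype (horizontal axis), of the tested members (points) of 16 gene lists (vertical axis), with the list median as a red line. The goblet list lies entirely above 0, with a median of 0.71, and the medians of the FoxO1 target and insulin and IGF lists lie near 0.

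Interferon, cell cycle, glycolysis and mesenchymal factor lists had small median shifts. Of 31 interferon genes 26 were higher (median 0.32, camera adjusted p = 0.0347, adjusted p = 0.908 with an estimated correlation), with log2 differences of 0.24 for Ifih1, 0.57 for Bst2, 0.43 for Oas1a and 0.48 for Irgm1. Of 37 cell cycle genes 27 were higher (median 0.10, camera adjusted p = 0.0489, adjusted p = 0.908 with an estimated correlation), Aurka by 0.32, Tyms by 0.39 and Ttk by 0.25, while Rrm2 differed by -0.26. Of 19 glycolysis genes 13 were lower (median -0.09, camera adjusted p = 0.0347, adjusted p = 0.908 with an estimated correlation), with Pkm at -0.29, Tpi1 at -0.20, Slc16a3 at -0.28 and Gpi1 at -0.17. Of 12 factors of the epithelial-mesenchymal transition 10 were lower (median -0.18, camera adjusted p = 0.0267, adjusted p = 0.77 with an estimated correlation), with Snai2 at -0.23, Tgfb1 at -0.18 and Itga5 at -0.28, and Tgfb3 at 0.25. In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone. With 1 tumour left out, the difference of the list means, 0.37 for interferon, 0.09 for cell cycle and -0.09 for glycolysis with all tumours, ran from -0.09 to 0.81, from 0.05 to 0.18 and from -0.17 to -0.01. Interferon lost its call without FoxO1ADA replicate 3 (camera adjusted p = 0.939), with array weights (0.117) and under the stricter filter (0.0526), and without wildtype replicate 2 its direction turned to lower (0.57). Mesenchymal factors lost it with no filter (0.122) and without wildtype replicates 1 (0.0861) and 3 (0.0651). Glycolysis lost it with no filter (0.0584), with array weights (0.116), without FoxO1ADA replicates 1 (0.0776) and 2 (0.0565) and wildtype replicates 1 (0.686) and 2 (0.134), and cell cycle without FoxO1ADA replicates 2 (0.258) and 3 (0.516) and wildtype replicates 1 (0.321) and 3 (0.437).

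FoxO1 target genes did not move together. Of 29 tested members 15 were higher and 14 lower, with a median log2 difference of 0.01 (camera adjusted p = 0.534). At an unadjusted p under 0.05, 5 of the 29 were higher and 2 lower, where 1059 of all 14529 tested genes reached it. Cited2 (0.56), Trp53inp1 (0.55), Gabarapl1 (0.42) and Pik3ip1 (0.34) were higher without overlap of the groups. Trib1 (-0.44) and the mitophagy receptor gene Bnip3 (-0.50) were lower without overlap. However, 0 members passed over all genes and 0 adjusted over the list alone. The insulin receptor substrate gene Irs2 read 6.35 ± 0.11 in FoxO1ADA and 6.39 ± 0.41 in wildtype tumours (SD, n = 3). Fry's test for changes in either direction gave the list an adjusted p of 0.0585. Of 34 insulin and IGF signalling genes 18 were higher (median 0.01, camera adjusted p = 0.905), with 0 past either threshold, over all genes or adjusted over the list alone. Its widest difference was in the IGF-binding protein gene Igfbp5, 1.46 on the log2 scale (10.1 ± 0.08 against 8.64 ± 0.66, SD, n = 3). Igfbp4 differed by 0.34, Akt1 by -0.17 and Rptor by -0.18.

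Tight junction, stem cell and signalling lists were not called by camera. Of 24 tight junction genes 11 were higher (median -0.01, mean 0.07, camera direction up, adjusted p = 0.884). The myosin light chain gene Myl9 (0.77), which smooth muscle also expresses, was the 1 member past the threshold adjusted over the list alone (limma adjusted p = 0.0168), with 0 over all genes. Cldn8 differed by 1.41, Cldn15 by 0.59 and Cldn4 by -0.46. Of 32 Wnt target and stem cell genes 10 were higher and 22 lower (median -0.11, camera adjusted p = 0.884), with Ephb3 at 0.39, Rgmb at 0.68, Lrig1 at 0.77 and Cd44 at -0.56. Of 24 STAT3 target genes 9 were higher, with a median of -0.02 and a mean of 0.30 (camera direction down, adjusted p = 0.884), and Reg3g, at 3.11, and Junb, at -0.39, were among the 4 with the smallest p. Of 25 cytokine and chemokine genes 10 were higher (camera adjusted p = 0.465), with Il23a at -1.04, Cxcl13 at 0.89, Cxcl5 at -0.66 and Ptgs2 at -0.36. In the Wnt, STAT3 and cytokine lists 0 members passed over all genes and 0 adjusted over the list alone.

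Lists of rarer epithelial cells, stromal and further immune cells and cell processes were not called by camera. Of 12 enteroendocrine genes 8 were higher (camera adjusted p = 0.66), and the transcription factor gene Isl1 (-0.94) and the tachykinin gene Tac1 (at least 0.935) made 2 past the threshold adjusted over the list alone, 0 over all genes. Of 14 epithelial cell genes 10 were lower (camera adjusted p = 0.0605), with 1 past the threshold adjusted over the list alone and 0 over all genes. Endothelial genes were higher in 12 of 17 cases (camera adjusted p = 0.12), with Tek at no less than 0.319 and Kdr at 0.48. In the extracellular matrix list the collagen VI genes Col6a3, Col6a2 and Col6a1 differed by -0.59, -0.41 and -0.34, while 17 of the list's 34 members were higher and 17 lower (median 0.00, mean 0.07, camera direction down, adjusted p = 0.96). Of 28 autophagy genes 14 were higher and 14 lower (camera adjusted p = 0.278), with Atg10 at 0.41, Atg12 at 0.28, Gabarapl1 at 0.42 and Atg13 at 0.33. In the p53 list Plk3 differed by -0.58 and Ccng1 by 0.67 (camera adjusted p = 0.884), and in the unfolded protein response list Ern2 by 0.76 and Edem1 by 0.45 (camera adjusted p = 0.131). Camera adjusted p was 0.0557 for monocytes and macrophages (13 of 17 higher), 0.0605 for MHC class II presentation (8 of 9), 0.278 for T and NK cells (9 of 14), 0.884 for dendritic cells (3 of 6), 0.884 for fibroblasts (5 of 13) and 0.561 for enteric neurons and glia (4 of 9). It was 0.884 for tuft cells (6 of 10 higher, median 0.01, mean -0.06) and 0.884 for adipocytes (4 of 8, median 0.01, mean -0.02), both with camera's direction down. It was 0.115 for cholesterol and fatty acid synthesis (11 of 27), 0.308 for oxidative phosphorylation (18 of 28) and 0.561 for fatty acid oxidation (14 of 24). Across the lists of this paragraph other than the enteroendocrine and epithelial ones, 0 members passed over all genes or adjusted over the list alone. The erythrocyte list had 1 tested member, Hba-a2 (-0.16), and was not tested as a list.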

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

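No group was large enough for an outlier test, which needs at least 4 samples, and the design has 1 contrast. 3 patterns were weighed, with tests chosen after their results were seen except those of colon position, MAPK output genes and the splits of the tumours.

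Immunoglobulin genes were higher in FoxO1ADA tumours, by a median of at least 6.11-fold over 153 clusters, of which 57 had a wildtype mean below the filter. A strain haplotype at the 3 loci, or probes shared between V segments, would leave genes outside the loci unmoved. The per-tumour mean of Jchain, Mzb1, Pou2af1, Tnfrsf17 and Derl3 was higher by 1.22 ± 0.33 (SE) on the log2 scale. All 5 were higher, Jchain by 3.68 and the others by 0.31 to 0.89. Tnfrsf17 lay below the filter, and the set was chosen after Jchain, Mzb1 and Pou2af1 were seen to be higher. The rise outside the loci thus argues only weakly against such a cause as the whole one for the set. Any single V segment stays open. Over the 153 clusters the wildtype mean was 4.52, 6.44 and 5.21 in replicates 1, 2 and 3. The kappa segments past the threshold were also highest in wildtype replicate 2. The heavy chain segments past it were not, at 2.21, 2.17 and 2.28 (start 113948282, below the filter) and 5.11, 4.72 and 4.94 (start 113685482). A cause particular to these heavy chain segments was not tested. Lymphoid follicles in the pieces would raise follicular B cell genes, whose mean was higher by 0.27 ± 0.14 (SE), but all 8 of these genes lay below the filter (mean 4.11), so follicles cannot be told apart from antibody-secreting cells here. A candidate explanation is more antibody-secreting cells in FoxO1ADA tumours, an effect of genotype that was not tested apart from the choice of tumour or from housing and microbiota, which the labels do not give.

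Goblet cell genes were higher in FoxO1ADA tumours, 23 of 23, by a median of 0.71 on the log2 scale. Non-tumour mucosa carried along would bring absorptive colonocyte genes too. The goblet mean minus the absorptive mean per tumour was higher by 0.83 ± 0.16 (SE, exact permutation p = 0.1), a contrast chosen after both list results were seen. The absorptive mean alone differed by -0.12 ± 0.27 (SE), too imprecise to exclude a rise. Goblet genes thus rose by more than absorptive genes, but mucosa in the pieces stays open. Muscle or lamina propria carried along also stays open for the smooth muscle, B and plasma cell and mast cell lists, which were also higher (medians 0.31, 0.84 and 1.22). Tumours taken from another position along the colon would differ in posterior Hox genes. The mean of Hoxb13, Hoxa13 and Hoxd10 to Hoxd13 differed by 0.094 ± 0.124 (SE), within the bound of 0.5 set before it was seen. That bound leaves room for a smaller shift, so a smaller difference in position stays open. The squamous list mean of wildtype replicate 2, 7.99 against 5.67 to 6.61 in the other tumours, was not tested against position. Variation between wildtype tumours stays open too, since wildtype replicate 2 had a goblet mean of 8.86, inside the FoxO1ADA range of 8.74 to 9.04. An effect of genotype on goblet cells was not tested apart from this variation, carried mucosa or a smaller difference in position. Goblet cell counts on sections of further tumours would test it.

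Immediate early genes were lower in FoxO1ADA tumours: 26 of 31 in a list written after Egr1 and Fosb were seen, and the 27 genes other than Egr1, Fosb, Klf6 and Csrnp1 had a mean difference of -0.22 ± 0.076 (SE). A difference in handling time before freezing would lower most of them together, and 22 of these 27 were lower, but their mean correlation within genotypes was 0.10, and the labels give no times. Lower MAPK pathway output would lower its other target genes, and all 8 tested (Spry2, Spry4, Etv4, Etv5, Spred1, Dusp4, Phlda1 and Epha2) were lower, by a mean of -0.28 ± 0.16 (SE), less than 2 standard errors from 0. Their differences ran from -0.06 (Etv4) to -0.57 (Epha2), and Dusp6, counted among the immediate early genes, differed by -0.04. The mean of the 8 in wildtype replicate 2, 7.06, lay inside the FoxO1ADA range of 6.89 to 7.11. Handling time and MAPK output cannot be told apart with 3 tumours per genotype and no recorded times.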

How the results depend on the processing

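The run without the immunoglobulin loci was chosen after seeing the data; the other alternatives were fixed beforehand. Against 7 genes past the adjusted threshold in limma, there were 14 with no filter, 3 with the stricter filter, 27 over all transcript clusters, where more immunoglobulin clusters entered, and 0 without the immunoglobulin loci (lowest adjusted p 0.0818, 1020 genes at an unadjusted p under 0.05). A plain equal-variance test called 0 (lowest adjusted p 0.117, 970 genes at an unadjusted p under 0.05). Leaving out 1 tumour gave 1 to 36 genes, with fewer samples in each fit. The replicate block left 1 gene; the mouse numbers share only a number, since deviations of same-numbered tumours correlated at 0.17, -0.06 and -0.19 and 2 of 6 tumours correlated best with their own number. Against 308 genes at 1.5-fold, the stricter filter gave 166, from fewer genes tested, and leaving out 1 tumour gave 252 to 628. The Foxo1 difference ran from -0.000997 to 0.173 and stayed uncalled, with a lowest adjusted p of 0.85. Against 12 called lists, the stricter filter gave 6 of 27 testable lists, camera with an estimated correlation 0 (2 at an unadjusted p under 0.05) and fry 0 (3 at an unadjusted p under 0.05); leaving out 1 tumour gave 9 to 15. The interferon list turned to a lower direction without wildtype replicate 2, at an adjusted p of 0.57, and the cause was not tested; leaving out 1 tumour moved its adjusted p between 4.41e-07 and 0.939. For Chad, Gal3st2 and Egr1, 24 of 44 values stayed past the threshold and 20 did not; for the named genes not past it, 10 of 1539 values rose past it; 0 of these 1583, which leave out Foxo1, turned in sign, while Foxo1, near 0, did without FoxO1ADA replicate 1. For the called lists, 151 of 200 values kept it and 48 lost it. Goblet, antimicrobial and B and plasma cell lists lost it only with the estimated correlation and fry, among alternatives that could test them. The remaining alternatives kept the preset correlation of 0.01, below the estimates of 0.385, 0.37 and 0.133 for these lists. Keeping the call under them therefore does not test that preset. With 6 tumours there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7 genes and the highest other 0 (1 of 10 as large), 308 genes at 1.5-fold against 293 (1 of 10), and 12 lists against 14 (5 of 10). The other splits called 10 to 14 lists each, so a count of 12 does not set the genotypes apart.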

Other observations

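Among annotated processes, the called terms were of defence, mostly against bacteria, and rested on alpha defensins, with other antimicrobial genes in some. Immunoglobulin genes were members of the Gram-negative term only. Of 722 biological process terms with 10 to 300 tested genes, 4 passed camera with the preset correlation, all of them upward defence terms, and 0 passed with an estimated correlation. Defense response to Gram-negative bacterium (16 genes) had a median log2 difference of 1.59 (adjusted p = 3.39e-10, adjusted p = 0.997 with an estimated correlation), and 9 of its genes were in none of the fixed lists. It holds 4 immunoglobulin genes and 6 alpha defensins, paralogs that can share probes. In a test chosen after these values were seen, immunoglobulin genes, alpha defensins and members of the antimicrobial list were left out of the 4 terms. The genes left in them (4, 22, 18 and 15) had medians of 0.56, 0.13, 0.13 and 0.18, and 0 of the 4 terms passed (lowest adjusted p = 0.389).

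Zinc finger genes of a cluster on chromosome 2 also had higher signals, and imprinted genes went both ways; both groups were assembled after the values were seen. Of 19 tested Zfp and Gm genes with starts from 174266428 to 178066878 on chromosome 2, 17 were higher and 2 lower, 13 of them at an unadjusted p under 0.05, with a median log2 difference of 0.43 and a per-tumour mean difference of 0.37 ± 0.11 (SE, exact permutation p = 0.1). Many of these genes are near-identical copies that can share probes, so they are not independent. Of 24 imprinted genes measured, 11 were higher and 13 lower, and 2 (H19 and Meg3, at 2.37 and 0.42) were higher at an unadjusted p under 0.05.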
